A study of Mus musculus with 3 samples.

How the data were processed

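Single cells from dissociated dental pulp and periodontium of mouse mandibular molars were sorted by fluorescence and loaded for droplet 3' RNA sequencing with unique molecular identifiers (UMIs), about 10000 cells per library, per the labels' protocols. There were 3 libraries, 1 per group: Cxcl12-GFP at day 6, Cxcl12-creER with a tdTomato reporter at day 6, and Col1a1-GFP with Cxcl12-creER at day 25. When tamoxifen was given is not in the labels used here. The authors deposited raw UMI counts per gene and barcode. Alignment to mm10 and use of Cell Ranger and Seurat are named in the submitters' processing notes, and the matrix headers name Cell Ranger 6.0.0 for Cxcl12-creER P6 and 3.1.0 for P25. The aligner settings and filters are not given in the sources used here. The feature lists held 28006 genes for Cxcl12-GFP P6 and P25, with reporter sequences, and 32286 for Cxcl12-creER P6. The 3 lists shared 27040 gene identifiers, which were used for every comparison with Cxcl12-creER P6. Of the Cxcl12-creER P6 barcodes, 82.3% began with 8 bases that also begin a P25 barcode, against 21.0% of the Cxcl12-GFP P6 barcodes, although the labels name the same chemistry for all 3 libraries. A difference in chemistry was not tested, and it would lie in every comparison with Cxcl12-GFP P6.

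Barcodes with at least 500 genes and at most 15% mitochondrial UMIs were kept, which left out 3 and 8 barcodes in Cxcl12-GFP P6, 536 and 24 in Cxcl12-creER P6 and 741 and 295 at P25. Doublets were scored with a reimplementation of the Scrublet scheme (2 simulated doublets per cell), and the highest scores were removed at a rate of 0.8% per 1000 cells, which took 452, 10 and 256 cells. The number removed follows from that rate and not from the scores. Counts were log-normalised, 2000 variable genes were chosen within 20 bins of mean expression, and 30 principal components and 15 neighbours gave a shared-neighbour graph for Leiden clustering at resolution 1.0, in each library alone (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9). Cxcl12, the reporters, mitochondrial and ribosomal genes and 11 pathway lists were left out of the variable genes. The clusters numbered 20, 27 and 31.

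Clusters were named from 20 marker lists. The markers were fixed before the data were examined, and the scoring rule and its thresholds were set after the clusters were seen and adjusted several times. They were loosened so that pulp-like cells at P25 took a name, and the limit on a second list was moved so that odontoblast-like cells kept theirs while an erythroid name was dropped from another cluster. A cluster took the best-scoring list with at least 3 markers at 1.5-fold or more above the median of the other clusters and detected in at least 10% of its cells, a mean log2 score of at least 0.9 and a lead of 0.3 over the next list. It stayed unnamed where a second list above 3.0 lay over 0.9 of the first, where its 30 or 10 leading genes held more markers of another list than its own, where cycling genes led, or where its median depth was under the library's divided by 3 with no own marker among the 10 leading genes. The dental follicle and periodontal ligament lists were joined into a single class, as were the coronal and apical papilla lists, and a cluster's own markers among its leading genes were counted over the joined class. Cluster 8 of Cxcl12-GFP P6 kept its ligament name with Ostn and Aldh1a2 against the bone markers Bglap and Bglap2, and cluster 19 of Cxcl12-creER P6 with Pthlh alone. One further naming condition and the results of 2 single genes are not reported here. A cluster led by the chondrocyte list with Col2a1 under 1000 CPM was called Col9a1-high mesenchymal, without the limits on score, lead and leading genes. Unnamed cells were 6.34%, 34.9% and 36.5% of the libraries. Because clusters led by cycling genes took no name, the proliferation list depends on the naming, and in osteoblast-like cells of Cxcl12-creER P6 its median over the other mesenchymal cells went from 1.85 to -0.76 without cluster 8. It is not read as a result of any class.

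With 1 library per group there was no test across samples, and no p-value was made from cells. Shares have exact (Clopper-Pearson) binomial 95% intervals, CPM of summed counts exact Poisson intervals, and ratios of CPM exact conditional binomial intervals, all for counting error only. Log2 ratios used a pseudocount of 1 CPM. A fold against a count of 0 was given as at least the value against 3 counts over the class. Classes with at least 50 cells in both libraries were compared, and at most 3 per comparison are described. Named genes were, by a rule fixed before the data were examined, Cxcl12, the reporters, the 8 highest and 8 lowest log2 ratios among genes with at least 50 CPM and 50 UMIs on the higher side (without mitochondrial, ribosomal, haemoglobin, sex-specific, Gm- and Rik-named genes), and up to 4 members of each described list with the largest log2 ratio at 20 CPM or more. The same rule was added after seeing the data without naming markers and without genes 4-fold or more apart in all 6 comparisons with Cxcl12-creER P6. The haemoglobin genes and Amelx, Ambn and Col1a1 were read as signs of free RNA or of other cells.

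The 14 gene lists, fixed before the data were examined, were proliferation, Wnt targets and antagonists, Wnt ligands, hedgehog, BMP and TGF-beta, FGF, Notch, niche factors, mineralisation, fibrillar and ligament matrix, dental mesenchyme transcription factors, hypoxia and glycolysis, interferon response, and immediate early and stress genes. A list's median log2 ratio was placed among 10000 random lists matched on mean expression in 20 bins, which describes these libraries only. For shares of cells with a UMI, each cell was also thinned to 1000 UMIs, which left out 0, 245 and 21 kept cells.

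The ratio and list steps were checked on simulated counts in which 100 genes changed 2-fold and 100 changed 4-fold. For P25 over Cxcl12-creER P6 in follicle or ligament-like cells, over 5360 genes, intervals covered the true value for 96.0% of genes changed 2-fold and 98.0% of those changed 4-fold, and excluded 1 for 4.44% of unchanged genes. For Cxcl12-GFP P6 over Cxcl12-creER P6 in Col9a1-high cells, over 6100 genes, the interval excluded 1 for 89.0% of genes changed 2-fold. Simulated lists of 15 unchanged genes fell outside the central 95% of random lists in 3.50% of 200 draws in both comparisons. Both sides were drawn with Poisson error from 1 profile, the model that the intervals assume. The simulation held no variation between cells, clusters or libraries, so it checks the calculation and gives no error rate for the real comparisons.

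Alternatives chosen before the data were examined were at least 1000 genes per cell, at most 10% mitochondrial UMIs, no doublet removal, resolutions 0.5 and 2.0, clustering the libraries together, means of per-cell CPM, ratios centred on the median of all genes, thinning, at least 2 reporter UMIs, and list members at 5 CPM. Added after seeing the data were naming by the best list alone, at least 5 reporter UMIs, CPM without enamel, haemoglobin and mitochondrial genes, and P25 cells with 5 tdTomato and under 5 GFP UMIs.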

Results

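The 3 libraries profiled single cells from mouse mandibular molars, sorted for reporters of Cxcl12 and, at the later age, also of Col1a1. Cxcl12 encodes a chemokine made by stromal cells (chromosome 6, 117168535 to 117181367, plus strand, GRCm38, ENSMUSG00000061353). One library held GFP-positive cells of Cxcl12-GFP mice at postnatal day 6 (Cxcl12-GFP P6). One held tdTomato-positive cells of Cxcl12-creER mice at day 6 (Cxcl12-creER P6), in which an inducible recombinase under Cxcl12 control switches on tdTomato. The other held GFP-positive, tdTomato-positive and doubly positive cells at day 25 (Col1a1-GFP Cxcl12-creER P25), where GFP reports the collagen gene Col1a1. Each group was 1 library, so no value below has a replicate error, and the 95% intervals in parentheses cover counting error only. The deposited matrices held 7528, 1691 and 6693 barcodes with 68891094, 6596256 and 99277096 UMIs, of which 7065, 1121 and 5401 cells were kept. Median depth was 8142, 1459 and 14792 UMIs per kept cell, so values from Cxcl12-creER P6 rested on far fewer molecules.

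Cells were first assigned to classes by marker genes, to ask which cell types each gate held. In Cxcl12-GFP P6, 3 mesenchymal classes made up most cells: 33.1% (32.1 to 34.3) were mesenchymal cells with high Col9a1, a cartilage-type collagen gene, and Col2a1 above other clusters but under 1000 CPM (556 of them in cluster 3, led by the papilla marker Smoc2), 29.0% (27.9 to 30.05) were papilla or pulp-like, and 28.8% (27.8 to 29.9) were follicle or ligament-like. Endothelial-like and mural-like cells made up 1.09% and 0.977%. In Cxcl12-creER P6, osteoblast or cementoblast-like cells were the largest named class at 16.1% (14.04 to 18.4), followed by dental epithelium-like cells at 11.6%, connective tissue fibroblast-like cells at 10.2%, follicle or ligament-like cells at 7.49% and Col9a1-high mesenchymal cells at 6.69%. At P25, ligament-like cells made up 17.2% (16.2 to 18.2), osteoblast or cementoblast-like cells 13.8%, pulp-like cells 11.7% (10.9 to 12.6), macrophage-like cells 3.85% and odontoblast-like cells 3.28%. Bone marrow stromal-like cells with Adipoq and Lepr were rare, at 0.537% or 29 cells. The sorts set these shares, and 6.34%, 34.9% and 36.5% of cells stayed unnamed. The share of osteoblast-like cells in Cxcl12-creER P6 was 0.0892% when the 3 libraries were clustered together, and the share of pulp-like cells in Cxcl12-GFP P6 was 16.9% at clustering resolution 0.5.

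**Figure D1:**
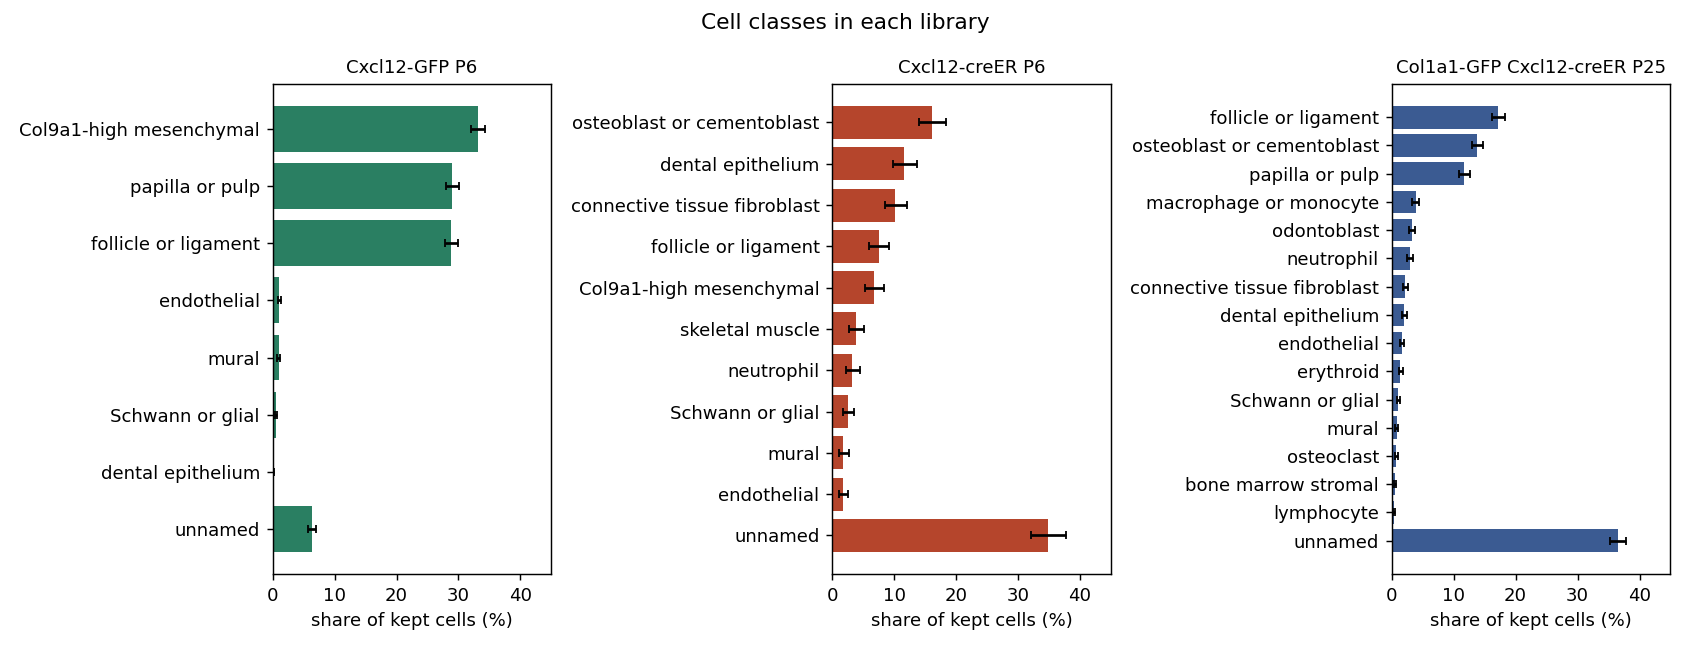
Share of kept cells (percent, horizontal axis) in each cell class (vertical axis), 1 panel per library. Bars are shares and black lines are exact binomial 95% intervals, and the 3 mesenchymal classes of Cxcl12-GFP P6 lie at 28.8% to 33.1%.

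Cxcl12 transcript was then compared between classes within each library. In Cxcl12-GFP P6, pulp-like cells carried the highest level, 437 CPM (427 to 447), against 176 CPM (170.0 to 182) in follicle or ligament-like cells, a ratio of 2.49 (2.39 to 2.59). Endothelial-like cells reached 350 CPM (308 to 396) and Col9a1-high cells 229 CPM (222 to 236). At P25 the ratio of pulp-like over ligament-like cells was 35.7 (33.3 to 38.4), with 1719 CPM (1686 to 1752) and 48.1 CPM (44.9 to 51.4). Cxcl12-GFP P6 was sorted on a Cxcl12 reporter, while P25 cells could also enter through Col1a1-GFP. Of the 928 P25 ligament-like cells, 602 had at least 5 GFP UMIs, so the ratios of these libraries are not compared. The highest level at P25 was 16712 CPM (16246 to 17189) in the 29 bone marrow stromal-like cells, and odontoblast-like cells, the dentin-forming layer of the tooth, carried 3.80 CPM (2.08 to 6.37), close to the 3.71 CPM of neutrophil-like cells. Endothelial-like cells at P25 had 575 CPM (531 to 621) and osteoblast-like cells 53.2 CPM (49.5 to 57.0). Among the named classes of Cxcl12-creER P6, connective tissue fibroblast-like cells were highest at 746 CPM (656 to 845), from 139 CPM in cluster 12 to 1455 CPM in cluster 13. Unnamed clusters 2 and 21 reached 1233 and 1483 CPM, and dental epithelium-like cells had 3.11 CPM from 4 UMIs.

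At least 1 Cxcl12 UMI was found in 98.1% (96.7 to 99.0) of P25 pulp-like cells and 37.8% (34.7 to 41.0) of ligament-like cells, at median depths of 9441 and 18533 UMIs. The background, taken from macrophage-like cells with a median of 13949 UMIs, was 14.9% (10.4 to 20.5). After each cell was thinned to 1000 UMIs, with none of these cells left out, the shares were 70.4% in pulp-like, 5.17% in ligament-like and 0.962% in macrophage-like cells. The P25 ratio of pulp-like over ligament-like cells was 8.62 when clusters were named by their best marker list alone, a choice made after seeing the data.

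**Figure D2:**
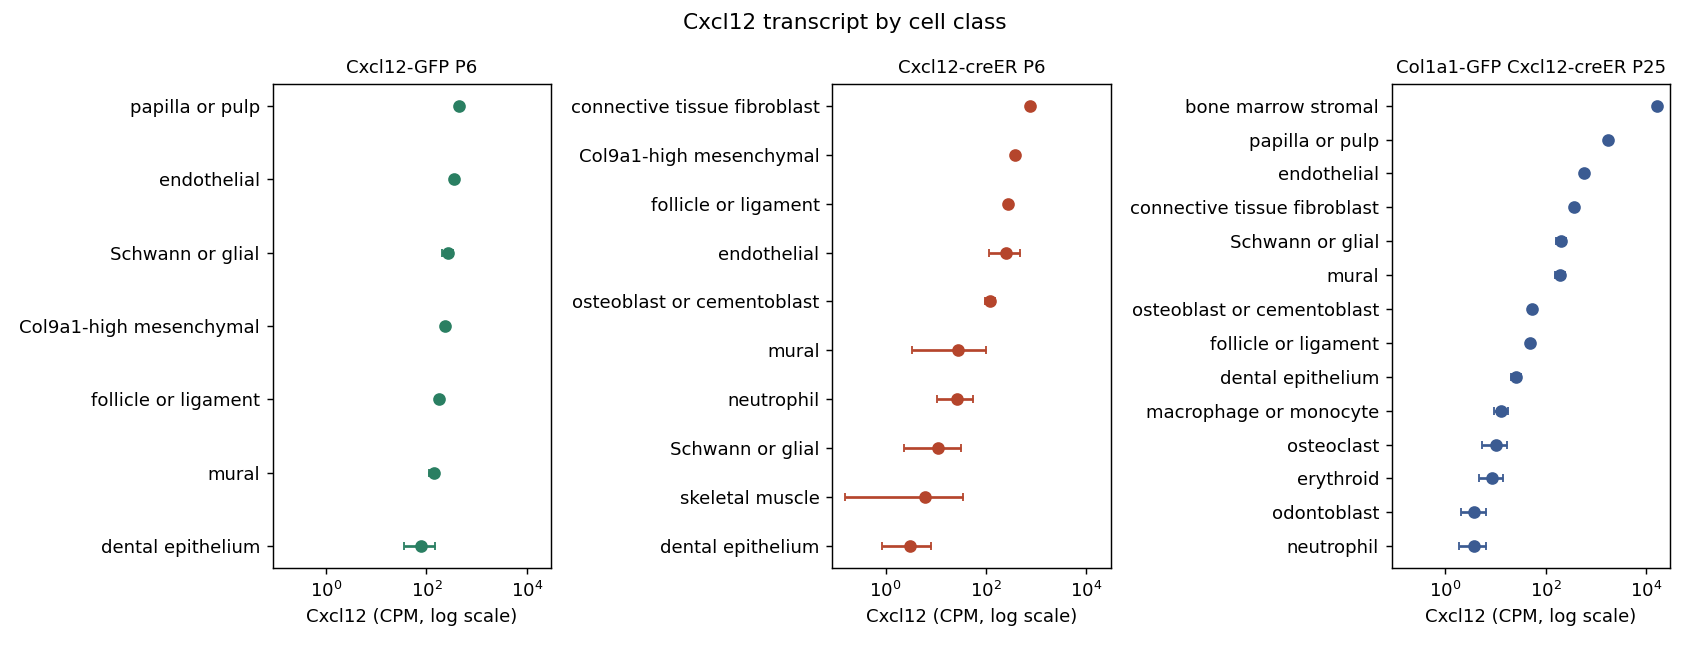
Cxcl12 level (CPM, log scale, horizontal axis) in each named class (vertical axis), 1 panel per library. Points are summed counts and lines are exact Poisson 95% intervals. Lymphocyte-like cells at P25 had 0 UMIs and are not drawn. Pulp-like cells lie at 437 CPM in Cxcl12-GFP P6 and 1719 CPM at P25.

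At P25 the tdTomato transcript, rather than the Col1a1-GFP transcript, set the named odontoblast-like class apart from the osteoblast-like clusters 2 and 5. Osteoblast-like cluster 18, of 95 cells, was lower in both. Of its cells, 17.9% had at least 5 GFP UMIs and 4.21% at least 5 tdTomato UMIs, against 67.2% and 52.0% of odontoblast-like cells. Unnamed cells, of which 34.1% had at least 5 tdTomato UMIs, were counted in neither the odontoblast-like nor the osteoblast-like class. Among the named classes, the Col1a1-GFP transcript was highest in odontoblast-like cells, at 3631 CPM (3570 to 3693), and osteoblast or cementoblast-like cells, at 3385 CPM (3355 to 3415), with 1412 CPM in ligament-like and 292 CPM in pulp-like cells. At least 5 tdTomato UMIs, a threshold chosen after seeing the data, were found in 52.0% (44.4 to 59.5) of odontoblast-like cells, 44.1% (40.2 to 48.1) of pulp-like cells, 22.7% (20.1 to 25.6) of ligament-like cells and 4.97% (3.52 to 6.78) of osteoblast-like cells, against 1 of 208 macrophage-like cells (0.481%, 0.0122 to 2.65). Other blood-lineage cells had more, with 33.1% (25.9 to 41.0) of neutrophil-like, 22.4% of erythroid-like and 10.0% of 20 lymphocyte-like cells. Among cells with at least 5 GFP UMIs, 49.6% (40.3 to 58.9) of 119 odontoblast-like cells also had 5 tdTomato UMIs, against 11.96% (9.48 to 14.8) of 602 ligament-like cells and 5.27% (3.56 to 7.48) of 550 osteoblast-like cells. Outside the tooth-forming mesenchyme, the share with 5 tdTomato UMIs was 79.2% in connective tissue fibroblast-like, 75.0% in mural-like, 70.0% in dental epithelium-like and 62.1% in Schwann-like cells. At least 5 GFP UMIs were found in 1.67%, 0%, 2.73% and 1.72% of these classes. Endothelial-like cells were lower, with 5 tdTomato UMIs in 12 of 86. Of the 5401 kept P25 cells, 1866 had under 5 UMIs of both reporters. Among them were 207 of 208 macrophage-like and 73 of 86 endothelial-like cells, against 24 of 120 connective tissue fibroblast-like cells. The reporter through which a cell entered thus cannot be read from these transcripts. The sort required either reporter, so the shares of these classes do not measure how often each cell type is marked. The same limit holds for pulp-like against osteoblast-like cells, of which 21.2% and 73.8% had 5 GFP UMIs.

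With 1 UMI as the threshold, tdTomato was found in 75.7%, 57.0%, 50.9% and 48.7% of odontoblast-like, pulp-like, ligament-like and osteoblast-like cells, and in 31.2% of macrophage-like cells, at median depths of 19016, 9441, 18533, 17923 and 13949 UMIs. Thinned to 1000 UMIs, the shares were 41.8%, 34.2%, 22.4%, 6.17% (4.54 to 8.17, with 16 cells left out) and 5.29% (2.67 to 9.27), and 25.6% in neutrophil-like cells, so the osteoblast-like share is not read as above background. In Cxcl12-creER P6, which was sorted for tdTomato, only 204 tdTomato UMIs were counted and 12.3% of kept cells had 1. The feature counted in that library was named tdTomato and in the other libraries tdT-WPRE, so these values are not compared. In Cxcl12-GFP P6, 93.1% of cells had a GFP UMI.

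**Figure D3:**
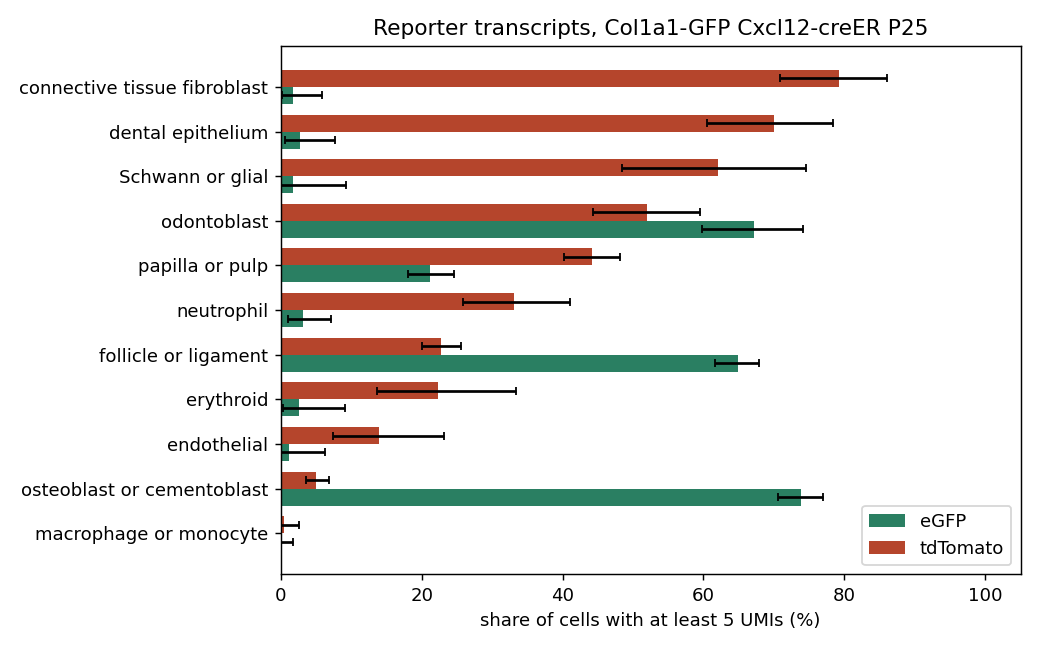
Share of P25 cells with at least 5 UMIs (percent, horizontal axis) of the Col1a1-GFP and tdTomato transcripts in each class of at least 50 cells (vertical axis). Bars are shares and black lines exact binomial 95% intervals, and osteoblast-like cells have GFP with a tdTomato share of 4.97%. Cells were sorted for either reporter, so the shares depend on the gate.

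Cells that express a Cxcl12 reporter were next compared with cells marked by Cxcl12-creER at the same age, in the 2 classes with at least 50 cells in both P6 libraries. Immediate early and stress genes, which respond within minutes to stimuli including tissue dissociation, were higher in Cxcl12-GFP P6: 14 of 14 measured members in Col9a1-high cells (median log2 ratio 2.02) and 14 of 14 in follicle or ligament-like cells (1.47), both at percentile 100 of 10000 random lists matched on expression. Fos was 9.20-fold higher (8.01 to 10.6) and Zfp36 7.14-fold higher in Col9a1-high cells, and Nr4a1 6.77-fold (5.24 to 8.91), Socs3 5.60-fold and Dusp1 4.97-fold higher in follicle or ligament-like cells. Cxcl12 itself was lower in Cxcl12-GFP P6, with log2 ratios of -0.74 in Col9a1-high cells and -0.64 in follicle or ligament-like cells, which is 1.67-fold (1.44 to 1.94) and 1.56-fold (1.39 to 1.75) higher in Cxcl12-creER P6. In follicle or ligament-like cells of Cxcl12-creER P6, most Cxcl12 UMIs lay in the cluster named dental follicle.

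The follicle or ligament-like class joined clusters named dental follicle and periodontal ligament in similar proportions of cells, though not necessarily of UMIs, in both P6 libraries. Of 84 Cxcl12-creER P6 cells, 49 were in a cluster named dental follicle. Of 2038 Cxcl12-GFP P6 cells, 882 were in clusters named periodontal ligament and the rest in clusters named dental follicle. Clusters inside the class were not separated, neither for Cxcl12 above nor for the values that follow. In this class, 9 of 11 hedgehog pathway genes were lower in Cxcl12-GFP P6 (median -0.66, percentile 1.38), among them the receptor gene Ptch1, 6.17-fold lower (5.69 to 6.69), and the effector Gli1, 2.34-fold lower. Of 15 Wnt targets and antagonists, 10 were lower (median -0.52, percentile 2.34), with Axin2 4.19-fold (2.95 to 5.86) and Lgr6 4.65-fold lower. The transcription factor genes of dental mesenchyme had a median of -0.29, with Twist1 4.85-fold lower and Lhx8 3.02-fold higher. The FGF pathway list had a median of -0.57 and the interferon list 0.72, at percentiles 14.9 and 88.6. In Col9a1-high cells, the Notch target Hes1 was 5.77-fold (4.28 to 7.98) and Id2, a BMP target, 4.75-fold higher, while Wnt6 was 8.85-fold and the proteoglycan gene Dcn 3.70-fold lower. Fibrillar and ligament matrix genes had medians of -0.28 and -0.32, at percentiles 0.770 and 0.435.

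The transcription factor gene Klf2 was 19.2-fold (12.6 to 31.0) higher in Col9a1-high cells and the chemokine gene Cxcl1 30.1-fold (17.9 to 55.1) higher in follicle or ligament-like cells of Cxcl12-GFP P6. The injury-response genes Rrad and Nupr1 were 28.4-fold (9.71 to 138) and 9.96-fold higher. The Wnt inhibitor gene Apcdd1 was 165-fold lower (83.5 to 372), and Kera, which encodes the tendon and cornea proteoglycan keratocan, had 1 UMI against 364 in follicle or ligament-like cells and led cluster 26, 11 of the 84 Cxcl12-creER P6 cells. Many of the extreme genes, such as Ptp4a1, Srp54b, Atp6v0c and Rnasek, lay far apart the same way in all 6 comparisons with Cxcl12-creER P6. Such genes numbered 43 in all. Ptp4a1 had 0 UMIs in these Cxcl12-creER P6 classes. Amelx, an enamel protein gene that ameloblasts express, was 13.5-fold higher in follicle or ligament-like cells of Cxcl12-creER P6 and took 9.13% of that library's UMIs. The follicle or ligament-like cells were clusters 1, 7, 8 and 10 in Cxcl12-GFP P6 and 6, 19 and 26 in Cxcl12-creER P6. With at most 10% mitochondrial UMIs the matrix median in that class turned to 0.12.

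P25 was compared with P6 in 3 classes per pair of libraries, where age and gate differ together. Follicle or ligament-like cells were not of the same kind at both ages: all 3 P25 clusters (0, 9 and 17) were named periodontal ligament, while cluster 6 of Cxcl12-creER P6, named dental follicle, held 49 of its 84 cells and 325 of 342 Cxcl12 UMIs. The median depth of that class was 14808.5 UMIs, far above its library. Against Cxcl12-creER P6, 8 of 13 mineralisation genes were higher at P25 (median log2 ratio 2.17, percentile 100) and 13 of 19 fibrillar and ligament matrix genes were higher (median 1.75, percentile 100). Col1a2 was 6.32-fold (6.18 to 6.46), Col3a1 6.05-fold and Sparc, a collagen-binding protein gene, 8.82-fold higher, and Mgp, an inhibitor of calcification, 70.2-fold (51.9 to 97.4) higher. Cxcl12 was 5.73-fold lower (5.04 to 6.51), but P25 clusters 0 and 9 carried 24.7 and 37.7 CPM and cluster 17 carried 272 CPM, with 405 of the 852 UMIs in 110 cells. Naming clusters by their best list alone gave a Cxcl12 log2 ratio of -1.06 rather than -2.49. The matrix median was 2.13 against cluster 6 and 1.75 against the 24 cells of cluster 19. Against the 11 cells of cluster 26 it was -1.22, and against clusters 19 and 26 together, both named periodontal ligament, -0.83 (-0.88 to -0.47). The 10 leading genes of cluster 19 held the follicle marker Pthlh and no ligament marker, so its name is weak. The mineralisation median against both was 2.11. The rises were not particular to this class. The mineralisation median was positive in every other class compared, and the matrix median in all but osteoblast-like cells. Against the same library the mineralisation and matrix medians were 2.74 and 3.16 in epithelium-like cells, where the median of all genes was 1.13, and 0.53 and 0.14 in fibroblast-like cells. Against Cxcl12-GFP P6 they were 2.05 and 0.74 in endothelial-like and 0.70 and 0.13 in pulp-like cells. The genes Tnn, Aspn, Postn, Bmp3 and Pthlh named this class and are not counted as findings of their own.

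The hedgehog, Wnt target, Notch and niche factor lists were lower in this comparison. All 11 hedgehog genes were lower (median -1.32, percentile 0.0400), with Ptch1 31.7-fold (28.0 to 35.9), Gli1 10.4-fold and the hedgehog inhibitor Hhip 148-fold lower. Of 15 Wnt targets and antagonists, 13 were lower (median -1.88, percentile 0), with Sostdc1 136-fold (108 to 173), Lef1 25.8-fold and Dkk2 24.3-fold lower. All 4 Notch genes were lower (median -1.87), Hes1 by 15.2-fold, as were 9 of 11 niche factors (median -1.40), with Lepr 13.6-fold and Igf1 5.30-fold lower. Against the 35 cells of clusters 19 and 26 alone, the hedgehog median was -1.04 (7 of 8 lower), the Wnt target median -0.84 (9 of 13), the Notch median -2.36 (3 of 3) and the niche factor median -0.59 (9 of 12). Counts of clusters 19 and 26 were summed here, and the matrix medians against each alone had opposite signs. The imprinted growth-linked RNA H19 was 104-fold lower. Tgfb1 was 9.94-fold (7.61 to 13.3), Fgfr3 9.35-fold and Lgals3, with 4006 UMIs against 0, at least 93.5-fold higher. The haemoglobin gene Hbb-bs was 10.4-fold and the bone gene Bglap 387-fold (107 to 3196) higher in these P25 cells. The Wnt ligand, BMP and hypoxia lists had medians of -1.39, -0.06 and -0.41, where the median of all genes at 20 CPM or more was -0.38. The BMP list is not read as apart from that shift. In P25 cells with at least 5 tdTomato and fewer than 5 GFP UMIs the Wnt ligand median turned to 0.27.

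Against Cxcl12-GFP P6, whose annotation matched that of P25, the same class gave a matrix median of 1.76 with 15 of 18 members higher (0.43 to 2.46 between single clusters), a mineralisation median of 2.07, a hedgehog median of -1.95 and a Notch median of -1.89 with 4 of 4 lower, while the median of all genes was -0.41. Cxcl12 was 3.66-fold lower (3.39 to 3.94), Foxf1 5.19-fold and Sostdc1 127-fold lower, and Mgp 508-fold (414 to 632) and Lgals3 31.2-fold higher. In P25 cells with at least 5 tdTomato and fewer than 5 GFP UMIs, 139 of the 928 cells, a choice made after seeing the data, the Cxcl12 log2 ratio was -0.29 rather than -1.85, and -0.94 rather than -2.49 against Cxcl12-creER P6. Of these 139 cells, 58 came from cluster 17, and in the other 81 it was -2.40 (-2.86 to -2.04) against Cxcl12-GFP P6. Naming by the best list alone gave -0.45, and clusters 0, 9 and 17 apart gave -2.78, -2.19 and 0.62. The immediate early list was higher at P25 against Cxcl12-creER P6 (median 0.82). Against Cxcl12-GFP P6 its median was -0.13, where that of all genes was -0.41, and it is not read as apart from that shift.

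Osteoblast or cementoblast-like cells carried more mineralisation transcripts at P25 than in Cxcl12-creER P6, where the class rests on clustering that library alone and shrank to 0.0892% of cells when the libraries were clustered together. Of 17 mineralisation genes, 15 were higher (median 1.95, percentile 100), with Phex, a phosphate-regulating endopeptidase gene, 12.1-fold (7.53 to 20.7) higher. All naming markers of the class, among them Bglap, Bglap2 and Spp1, are members of this list. Its median and percentile thus depend on the naming, which the random lists do not correct for. Matrix genes were lower in 13 of 18 (median -1.18), with Col12a1 11.8-fold (10.9 to 12.8), Fmod 14.4-fold and Aspn 15.2-fold lower. Igf1 was 15.4-fold and Tgfb2 54.8-fold lower, while Dkk1, a secreted Wnt inhibitor gene, was 13.2-fold (5.66 to 40.8) and Tnfsf11, which encodes the osteoclast factor RANKL, 10.8-fold (2.97 to 89.1) higher. Cxcl12 was 2.28-fold lower (1.77 to 2.91), and the median of all genes was -0.45. The cells were clusters 2, 5 and 18 at P25 and 7, 8, 9 and 10 at P6, with median depths of 17923 and 1315 UMIs. Naming clusters by their best list alone turned the Cxcl12 log2 ratio from -1.18 to 0.42. The proliferation median was -3.27 over 16 genes, but clusters led by cycling genes had been set aside, while cluster 8 of Cxcl12-creER P6, with Rrm2 and Ccne2 among its leading genes, was kept. Without cluster 8 only 3 of these genes were measured (median -1.76), so no change in proliferation is read from this list.

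Summed over cells, epithelium-like cells were of different kinds at the 2 ages, and the P6 clusters 1 and 11 were not separated. At P6 the sum carried ameloblast transcripts, with the naming marker Amelx at 440656 CPM. Mmp20, an enamel protease gene, and Calb1 were 1004-fold and 2410.1-fold lower at P25. At P25 Krt13 and Ly6d, genes of lining epithelium, had 3978 and 2428 UMIs against 0 each, at least 639-fold and 390.3-fold higher. Cxcl12 was 8.44-fold higher (3.15 to 31.8), from 70 and 4 UMIs, with a UMI in 14 of 110 P25 cells, 2 or more in only 6 of them, and 26.2 CPM against 13.2 CPM in P25 macrophage-like cells. The median of all genes was 1.13, and the Cxcl12 log2 ratio relative to it was 1.60. The cells were cluster 16 at P25 and 1 and 11 at P6. Hbb-bs was 1211-fold higher and Spp1 571-fold higher in these P25 cells.

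In pulp-like cells, P25 was compared with Cxcl12-GFP P6. Cxcl12 was 3.93-fold (3.82 to 4.06) higher at P25, where both clusters were named coronal papilla. At P6 the class also held an apical papilla cluster of 258 cells with 166 CPM, and its other clusters had 274 to 650 CPM. Apod, which encodes a lipid-binding protein, was 48.5-fold (46.8 to 50.3), Inmt, a methyltransferase gene, 217-fold (147 to 332) and Syn3 46.8-fold higher, while Lect1, an angiogenesis inhibitor gene, was 174-fold (67.9 to 640.3), H19 159.9-fold, Pcp4 61.6-fold and Gfra2, a neurotrophic factor receptor gene, 25.7-fold lower. Interferon response genes were higher in 7 of 8 (median 1.06, percentile 99.8), with Isg15 3.48-fold (3.103 to 3.91) and Ifit1 3.46-fold higher, and immediate early genes in 15 of 16 (median 1.48), with Jun 5.46-fold higher. Wnt targets and antagonists were lower in 5 of 7 (median -1.17, percentile 0.0400), with Sfrp1 5.24-fold and Nkd1 3.84-fold lower, and the roof-plate Wnt agonist Rspo4 was 9.05-fold lower. Notch1 was 5.79-fold, Foxc1 9.19-fold and Twist1 9.14-fold higher. The bone genes Spp1 and Bglap rose 256-fold and 57.6-fold, and Hbb-bs 14.1-fold. The cells were clusters 3 and 6 at P25 and 0, 2, 9 and 12 at P6, and the median of all genes was -0.18. At clustering resolution 0.5 the Cxcl12 log2 ratio was 0.67 rather than 1.97, the interferon median 0.01 and the Wnt target median 0.99, with Pcp4 at 2.45 and Nkd1 at 0.56.

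In endothelial-like cells, 86 at P25 and 77 in Cxcl12-GFP P6, all 13 interferon response genes were higher at P25 (median 2.54, percentile 100), including Ifit3, 40.1-fold (10.9 to 335), Ifi44, 22.4-fold, and Irf7, 17.5-fold. The coagulation factor gene F8 and the adhesion molecule gene Selp were at least 42.3-fold and 30.3-fold higher, with 0 UMIs at P6. The connexin gene Gja5 was 46.5-fold (19.5 to 145), Bmx 40.7-fold and Gkn3 at least 47.5-fold lower, and the Notch list had a median of -1.24 with 4 of 6 lower, Hey1 by 17.7-fold, while the ligand gene Dll1 was 4.36-fold higher. Cxcl12 was 1.64-fold higher (1.42 to 1.91) in summed counts, but fewer P25 cells had a UMI (48.8% against 80.5%, or 27.9% against 36.4% after thinning to 1000 UMIs). Pf4, a gene of platelets and macrophages, had 108 UMIs against 0, and Bglap 235 against 0. The cells were cluster 21 at P25 and cluster 15 at P6, and kinds of endothelial cell inside them were not separated. The P6 cells were sorted on a Cxcl12 reporter, while 73 of the 86 P25 cells had under 5 UMIs of both reporters. A different mix of endothelial cells thus cannot be told apart from a change within them.

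**Figure D4:**
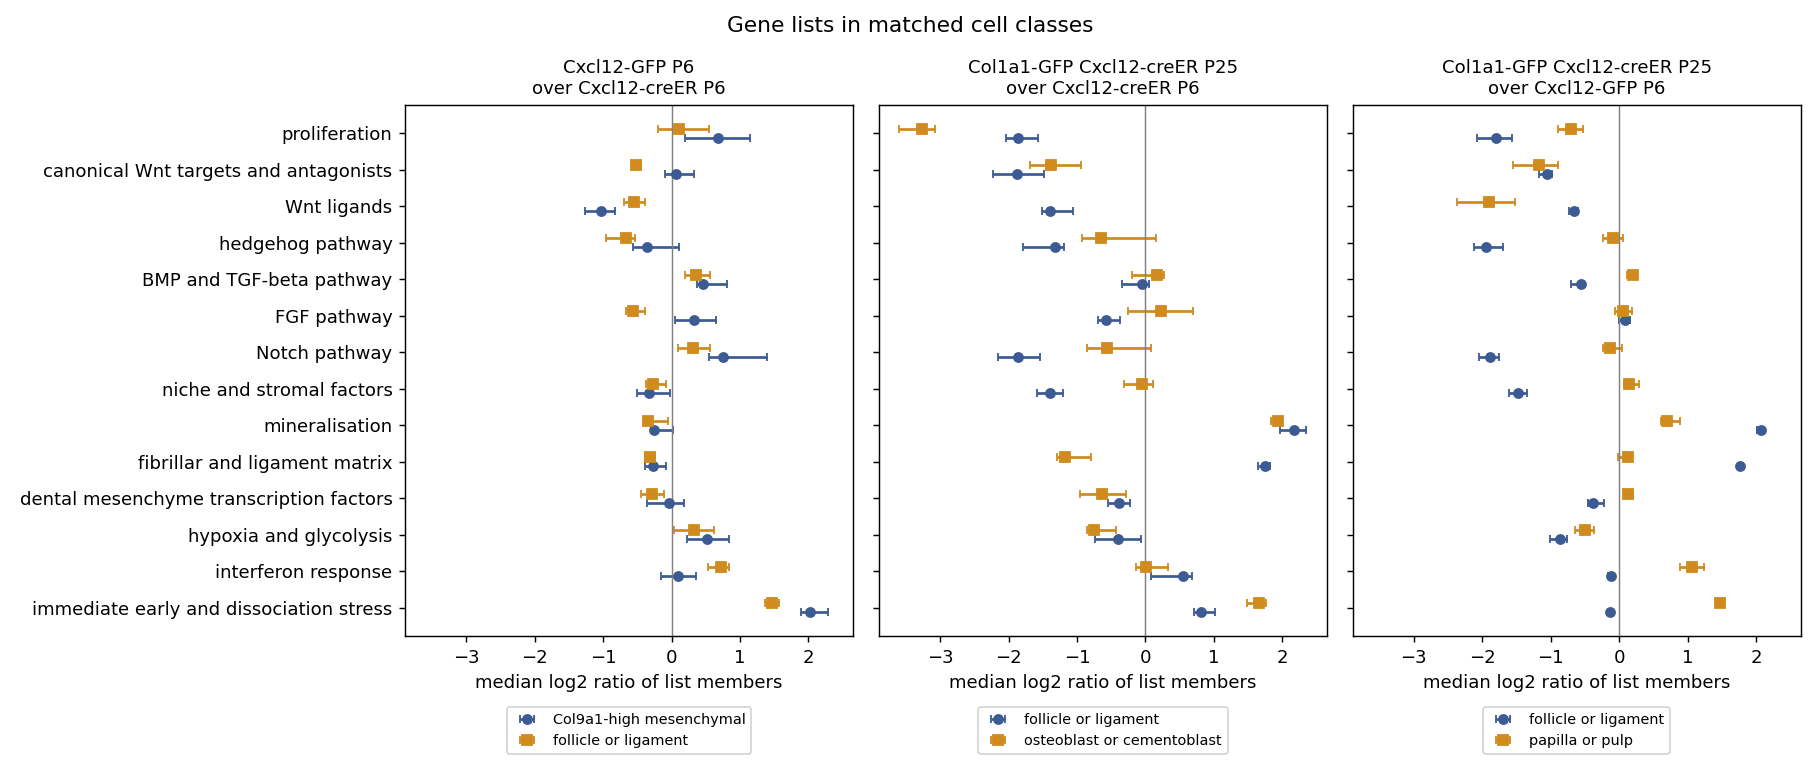
Median log2 ratio of the measured members of each gene list (horizontal axis) for the 2 largest matched classes of each pair of libraries. Points are medians and lines are 95% intervals from Poisson redraws of the counts. In follicle or ligament-like cells the matrix list lies at 1.75 and 1.76 in the comparisons of P25 with the P6 libraries.

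Within single libraries, pathway genes that were kept out of the clustering set the mesenchymal classes apart. In Cxcl12-GFP P6, 11 of 12 Wnt targets and antagonists were higher in follicle or ligament-like cells than in the other mesenchymal cells (median 1.88, percentile 100) and 12 of 12 were lower in pulp-like cells (median -1.63), while the Notch list was higher in pulp-like cells (median 1.11, 5 of 6) and lower in follicle or ligament-like cells (median -1.36). Hedgehog genes followed the follicle or ligament-like cells (median 0.78, 6 of 8) and in Cxcl12-creER P6 11 of 11 were higher there (median 0.78). The immediate early list was higher in that class too (medians 0.60 and 0.79). At P25, where osteoblast-like, odontoblast-like and fibroblast-like cells were also among the others, that class had a hedgehog median of -0.09 with 3 of 7 higher and a Wnt target median of -0.15 with 5 of 11 higher. Its immediate early median at P25 was -0.90, with 15 of 16 lower. Wnt targets were lower in P25 pulp-like cells than in the other P25 mesenchymal cells (median -1.40, 7 of 9 lower). The reference cells differ between the ages, so these medians are not compared. Also at P25, all 7 Notch genes and all 8 interferon genes were higher in pulp-like cells (medians 2.70 and 1.95), as were 14 of 16 immediate early and stress genes (median 1.33) and 15 of 18 BMP and TGF-beta genes (median 1.62), and 5 of 6 Wnt ligand genes were higher in odontoblast-like cells (median 1.69), for which Wnt10a was a naming marker. The connective tissue fibroblast-like cells at P25 had the highest FGF list of the 5 mesenchymal classes compared (median 1.997, 7 of 10 higher).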

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

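The tests of this pattern were all chosen after the result was seen. The Cxcl12-GFP P6 library held 1480 tdTomato UMIs and 858 iCreER UMIs, although its label names neither allele, and both lie above the limit that a count of 0 allows. At least 1 tdTomato UMI was found in 17.6% of its cells, or 2.46% after thinning to 1000 UMIs, and at least 1 iCreER UMI in 5.36%. Endothelial-like cells had 60.2 CPM of tdTomato and pulp-like cells 20.02 CPM, while iCreER reached 34.1 CPM in Col9a1-high cells and 2.98 CPM in follicle or ligament-like cells.

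Free RNA from 1 source would keep both transcripts in 1 ratio in every class, but the iCreER to tdTomato ratio was 8.78 times (6.53 to 11.8) as high in Col9a1-high as in follicle or ligament-like cells. Reads of the GFP transcript counted as tdTomato would keep those in 1 ratio, which differed 1.67 times (1.21 to 2.31) between endothelial-like and pulp-like cells. Molecules carried over from the P25 library would bring its barcodes, and 0% (up to 0.297%) of the 1241 tdTomato-positive cells had one. These 2 libraries shared 1 barcode in all, and 21.0% of the Cxcl12-GFP P6 barcodes began with 8 bases that also begin a P25 barcode, against 82.3% for Cxcl12-creER P6. The barcode sets thus appear to differ, shared barcodes were not to be expected, and this last test decides nothing. Alleles that the label leaves out, or a mixed sample, stay open and were not tested, and no biological explanation was tested.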

How the results depend on the processing

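GFP P6, creER P6 and P25 stand here for the 3 libraries, and follicle, pulp, osteoblast, fibroblast, epithelium and endothelium for the classes of the report. Naming by the best list alone, at least 5 reporter UMIs, CPM without enamel, haemoglobin and mitochondrial genes, and P25 cells with 5 tdTomato and under 5 GFP UMIs were chosen after seeing the data, and the other alternatives before. For the 31 values that answer a comparison, 126 alternative values lay inside the counting interval of the reported one. Outside it, 128 did not turn round and 2 did. A share of cells has no side, so it cannot turn round however far it moves. The osteoblast share of creER P6 with the libraries clustered together is such a case. The number that turned round is thus not a measure of stability. For the 362 values of single genes and other lists, the counts were 2068, 1228 and 19. These counts cover every value, including those left out of the text. The intervals are narrow because they cover counting error alone. The matrix median in follicle cells stayed between 1.496 and 2.06 for P25 over creER P6 under the alternatives that moved it, and between 1.48 and 1.82 over GFP P6. These alternatives do not part the clusters of the class: over the clusters of creER P6 named periodontal ligament it was -0.83. Those clusters, taken singly, gave medians of opposite sign. CPM without enamel, haemoglobin and mitochondrial genes left 17 of 17 such values inside their intervals. For every value given next the cause was not tested.

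With at least 1000 genes per cell, shares were 31.9% (Col9a1-high, GFP P6). Cxcl12 CPM ratios were 2.32 (pulp over follicle, GFP P6). Cxcl12 log2 ratios were -1.69 (osteoblast, P25 over creER P6). List medians were -0.18 (matrix, follicle, GFP P6 over creER P6), 1.88 (matrix, follicle, P25 over creER P6) and 1.81 (matrix, follicle, P25 over GFP P6).

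With at most 10% mitochondrial UMIs, shares were 31.5% (Col9a1-high, GFP P6), 30.7% (pulp, GFP P6), 13.7% (osteoblast, creER P6) and 19.7% (follicle, P25). CPM ratios of Cxcl12 were 2.21 (pulp over follicle, GFP P6), 29.0 (pulp over follicle, P25) and 2.12 (fibroblast over follicle, creER P6). Shares of cells with a Cxcl12 UMI were 84.5% (pulp, GFP P6). Log2 ratios of Cxcl12 were -0.38 (Col9a1-high, GFP P6 over creER P6), -2.23 (follicle, P25 over creER P6), 2.10 (pulp, P25 over GFP P6) and -1.60 (follicle, P25 over GFP P6). List medians were 1.81 (immediate early, Col9a1-high, GFP P6 over creER P6), 0.12 (matrix, follicle, GFP P6 over creER P6), -1.98 (hedgehog, follicle, P25 over creER P6), 2.06 (matrix, follicle, P25 over creER P6) and -1.29 (proliferation, osteoblast, P25 over creER P6). They were also -1.45 (hedgehog, follicle, P25 over GFP P6) and 1.56 (matrix, follicle, P25 over GFP P6). Single genes turned to 0.63 (Col14a1, follicle, GFP P6 over creER P6), 0.95 (Col14a1, follicle, P25 over creER P6), 1.84 (Rrm2, osteoblast, P25 over creER P6) and 0.82 (Ccna2, osteoblast, P25 over creER P6).

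With no doublet removal, shares were 24.6% (Col9a1-high, GFP P6), 19.1% (pulp, GFP P6), 11.9% (osteoblast, creER P6) and 21.9% (follicle, P25). Cxcl12 CPM ratios were 2.78 (pulp over follicle, GFP P6) and 20.9 (pulp over follicle, P25). Cells with a Cxcl12 UMI made up 88.4% (pulp, GFP P6). Cxcl12 log2 ratios were -0.45 (Col9a1-high, GFP P6 over creER P6), -1.75 (follicle, P25 over creER P6), -1.17 (follicle, P25 over GFP P6), 1.72 (pulp, P25 over GFP P6) and 0.45 (endothelium, P25 over GFP P6). List medians were 1.80 (immediate early, Col9a1-high, GFP P6 over creER P6), -1.09 (hedgehog, follicle, GFP P6 over creER P6), -0.21 (matrix, follicle, GFP P6 over creER P6), 1.59 (matrix, follicle, P25 over creER P6) and -1.71 (proliferation, osteoblast, P25 over creER P6). They were also -1.65 (hedgehog, follicle, P25 over GFP P6), 1.82 (matrix, follicle, P25 over GFP P6) and 0.87 (interferon, pulp, P25 over GFP P6). Single genes turned to 1.05 (Top2a, osteoblast, P25 over creER P6) and 0.83 (Ccna2, osteoblast, P25 over creER P6).

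At resolution 0.5, shares were 45.4% (Col9a1-high, GFP P6), 16.9% (pulp, GFP P6), 15.2% (follicle, P25) and 17.9% (pulp, P25). CPM ratios of Cxcl12 were 3.19 (pulp over follicle, GFP P6) and 33.0 (pulp over follicle, P25). Shares of cells with a Cxcl12 UMI were 81.6% (pulp, P25) and 93.9% (pulp, GFP P6). Shares of P25 cells with tdTomato were 62.01% (pulp). Log2 ratios of Cxcl12 were -3.27 (follicle, P25 over creER P6), -2.66 (follicle, P25 over GFP P6) and 0.67 (pulp, P25 over GFP P6). List medians were -0.54 (hedgehog, follicle, GFP P6 over creER P6), 1.63 (matrix, follicle, P25 over GFP P6), 0.99 (Wnt target, pulp, P25 over GFP P6), 2.29 (Wnt ligands, pulp, P25 over GFP P6) and 0.0058 (interferon, pulp, P25 over GFP P6). Single genes turned to 3.06 (Tac1, pulp, P25 over GFP P6), 2.45 (Pcp4, pulp, P25 over GFP P6), 0.56 (Nkd1, pulp, P25 over GFP P6) and 2.62 (Tcf7, pulp, P25 over GFP P6). Others turned to 1.08 (Rspo2, pulp, P25 over GFP P6) and -0.22 (Ifit3, pulp, P25 over GFP P6).

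At resolution 2.0, shares were 25.3% (Col9a1-high, GFP P6), 20.5% (pulp, GFP P6), 22.1% (osteoblast, creER P6) and 25.6% (follicle, P25). Cxcl12 CPM ratios were 2.68 (pulp over follicle, GFP P6) and 22.5 (pulp over follicle, P25). Cells with a Cxcl12 UMI made up 88.7% (pulp, GFP P6). Cxcl12 log2 ratios were -1.84 (follicle, P25 over creER P6), -1.32 (follicle, P25 over GFP P6) and 1.74 (pulp, P25 over GFP P6). List medians were -0.40 (matrix, follicle, GFP P6 over creER P6), 1.59 (matrix, follicle, P25 over creER P6), -3.02 (proliferation, osteoblast, P25 over creER P6), -1.43 (hedgehog, follicle, P25 over GFP P6) and 1.68 (matrix, follicle, P25 over GFP P6). They were also 0.86 (interferon, pulp, P25 over GFP P6).

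With the 3 libraries clustered together, shares were 35.1% (pulp, GFP P6), 0.0892% (osteoblast, creER P6), 10.6% (follicle, P25) and 15.9% (pulp, P25).

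With means of per-cell CPM, Cxcl12 CPM ratios were 31.9 (pulp over follicle, P25). Log2 ratios of Cxcl12 were -0.97 (Col9a1-high, GFP P6 over creER P6), -2.08 (follicle, P25 over creER P6), -0.62 (osteoblast, P25 over creER P6), -1.54 (follicle, P25 over GFP P6) and 2.11 (pulp, P25 over GFP P6).

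With ratios centred on the median of all genes, Cxcl12 log2 ratios were -2.12 (follicle, P25 over creER P6), -0.73 (osteoblast, P25 over creER P6), 1.60 (epithelium, P25 over creER P6), -1.44 (follicle, P25 over GFP P6) and 2.16 (pulp, P25 over GFP P6).

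With cells thinned to 1000 UMIs, shares of cells with a Cxcl12 UMI were 70.4% (pulp, P25) and 35.1% (pulp, GFP P6). Among P25 cells, shares with tdTomato were 41.8% (odontoblast), 34.2% (pulp), 22.4% (follicle) and 6.17% (osteoblast).

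With at least 2 reporter UMIs, shares of P25 cells with tdTomato were 64.4% (odontoblast), 48.3% (pulp), 33.2% (follicle) and 25.2% (osteoblast).

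With list members at 5 CPM or more, list medians were 1.83 (immediate early, Col9a1-high, GFP P6 over creER P6), -3.04 (proliferation, osteoblast, P25 over creER P6) and 0.73 (interferon, pulp, P25 over GFP P6).

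With clusters named by the best list alone, shares were 33.8% (follicle, P25) and 15.4% (pulp, P25). Cxcl12 CPM ratios were 8.62 (pulp over follicle, P25). Cells with a Cxcl12 UMI made up 88.0% (pulp, P25). Among P25 cells, shares with tdTomato were 55.8% (follicle). Log2 ratios of Cxcl12 were -1.06 (follicle, P25 over creER P6), 0.42 (osteoblast, P25 over creER P6), -0.45 (follicle, P25 over GFP P6) and 1.34 (pulp, P25 over GFP P6). List medians were -0.23 (matrix, follicle, GFP P6 over creER P6), 1.496 (matrix, follicle, P25 over creER P6), -1.23 (hedgehog, follicle, P25 over GFP P6), 1.49 (matrix, follicle, P25 over GFP P6) and 0.64 (Wnt ligands, pulp, P25 over GFP P6). They were also 0.41 (interferon, pulp, P25 over GFP P6). Single genes turned to 0.57 (Sfrp2, osteoblast, P25 over creER P6) and 0.12 (Angpt1, follicle, P25 over GFP P6).

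With at least 5 reporter UMIs, shares of P25 cells with tdTomato were 52.0% (odontoblast), 44.1% (pulp), 22.7% (follicle) and 4.97% (osteoblast).

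In P25 cells with at least 5 tdTomato and under 5 GFP UMIs, Cxcl12 log2 ratios were -0.94 (follicle, P25 over creER P6), -0.29 (follicle, P25 over GFP P6) and 1.89 (pulp, P25 over GFP P6). List medians were 0.27 (Wnt ligands, follicle, P25 over creER P6), -1.07 (hedgehog, follicle, P25 over creER P6), 1.57 (matrix, follicle, P25 over creER P6), -1.504 (hedgehog, follicle, P25 over GFP P6) and 1.48 (matrix, follicle, P25 over GFP P6). They were also 1.501 (interferon, pulp, P25 over GFP P6).

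With at least 1000 genes per cell, the Col9a1-high comparison of the P6 libraries and the epithelium comparison gave no value, since fewer than 50 cells remained in a class. Clustering the libraries together was used for shares only, and per-cell means and centring were not applied to the lists. No paired analysis was possible because each group was 1 library. Depth limited the values of creER P6 most, with a median of 1459 UMIs per cell (14808.5 in follicle cells), and 245 of its cells fell below the thinning depth.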

Other observations

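The tests of annotation, free ameloblast RNA and cluster subtypes were chosen before their results were seen, and the tests of the Col1a1-GFP gate and of single clusters after. The 6 comparisons with Cxcl12-creER P6 used its follicle or ligament-like cells against both other libraries, so they are not 6 separate classes. Across them, 43 of 27040 shared genes lay 4-fold or more apart the same way, 9 higher and 34 lower than in that library. Of these, 46.5% (31.2 to 62.3) overlap on the same strand a gene that only 1 of the 2 annotations lists, against 3.24% (3.03 to 3.46) of the other shared genes. Free ameloblast RNA would put most of the 34 lower genes at 2-fold or more in dental epithelium-like cells, where 5.88% (0.720 to 19.7) were. Different gene annotations are a candidate explanation for part of these genes, while the genes without such an overlap stay open.

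Follicle or ligament-like cells had a matrix median of 1.76 and a Cxcl12 log2 ratio of -1.85 in P25 over Cxcl12-GFP P6. In P25 cells with at least 5 tdTomato and under 5 GFP UMIs, the matrix median was 1.48 (1.42 to 1.54). Most of this median thus remained in cells with little GFP transcript, a stand-in for the sort gate. In the 81 such cells of clusters 0 and 9 it was 1.37 (1.30 to 1.43), against 1.73 in all cells of these clusters. Between clusters named periodontal ligament fibroblast in both libraries, 928 and 882 cells, it was 1.45 (1.41 to 1.49), and over the 35 cells so named in Cxcl12-creER P6 -0.83 (-0.88 to -0.47). The clusters of those 35 cells, taken singly, gave medians of opposite sign. Of the 882 cells, 472 lay in a cluster with Bglap and Bglap2 among its leading genes. That test kept every P25 cell of the class, so it left the P25 clusters mixed. Between single clusters the lowest median was 0.43 (0.39 to 0.51), for P25 cluster 9 over cluster 10 of Cxcl12-GFP P6, so a different mix of clusters stays open. In the same pair of libraries the list had a median of 0.13 (-0.01 to 0.16) in pulp-like and 0.74 (0.41 to 1.03) in endothelial-like cells, so it did not move alike in every class. Free RNA was not tested. Age is named by the design and stays open, untested, since age and gate differ together.

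For Cxcl12 in the same cells, the log2 ratio was -0.29 (-0.46 to -0.13) in those P25 cells and -2.05 (-2.19 to -1.95) between the clusters named periodontal ligament. The second test again kept every P25 cell. Of the 139 gated cells 58 came from cluster 17, and in the 81 from clusters 0 and 9 the log2 ratio was -2.40 (-2.86 to -2.04), against -2.63 in all cells of these clusters. Inside clusters 0 and 9 most of the lower level thus remained in these cells. UMI counts only stand in for the P25 sort gate. Cxcl12-GFP P6 was itself sorted on a Cxcl12 reporter, and this test does not reach that gate. P25 cluster 17 lay above Cxcl12-GFP P6 (0.93, 0.74 to 1.13, over its cluster 7), while clusters 0 and 9 lay below. For the class as a whole the gate and the mix of clusters cannot be told apart, because the gate changes that mix. Selecting tdTomato-positive cells of a Cxcl12-creER line also selects on past Cxcl12 expression, which this test does not separate from the gate.

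At P25, 2 unnamed clusters carried much tdTomato. One of 442 cells, led by Sfrp2, Pmch and Igfbp3, had 5 tdTomato UMIs in 60.2% of its cells and 340.05 CPM of Cxcl12. One of 134 cells, led by Col26a1, Aox3 and Tac1, had them in 75.4% with 50.2 CPM of Cxcl12. Another unnamed cluster of 253 cells, led by Cxcl10 and Bdnf, had 825 CPM of Cxcl12.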
